A study of Oryza sativa Indica Group and Oryza sativa Japonica Group with 8 samples.

How the data were processed

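Total RNA from young panicles of AnN, AnS-1, ZH11 and Os02g12290iL1, each at 2 temperatures, had been hybridised to 8 arrays, 1 per line and temperature. Per the labels, RNA was extracted with Trizol and a Qiagen kit and labelled as biotinylated cRNA. The deposited values are intensities, 1 per probe set and array, made with Affymetrix Expression Console and RMA per the submitters' processing notes, and no version is given in the sources used here. RMA usually gives log2 values, but the deposited ones were linear, so the unit was taken from the values themselves. Their quantiles fell into 3 sets of arrays (indica low, indica high and japonica) that lay on different scales, and how each set was scaled is not given in the sources used here. All 8 value columns were used, and 0 were left unused. No centring of probe sets was seen, since the levels of probe sets differ within each array.

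The design named 2 groups of genotype at 2 temperatures, wild type (AnN, ZH11) and tms5 (AnS-1, Os02g12290iL1), with 2 arrays in each of the 4 groups. The background (indica or japonica), known from the organism and line, was the block. The groups, comparisons, tests, thresholds, gene list themes, alternatives and the rule for named genes were fixed before the data were examined, except where stated here. The design had foreseen log2 RMA values. Quantile normalization was chosen once the 3 scales were seen and before any comparison was computed.

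The 57258 probe sets were quantile normalized on the linear scale. Then 64 control probe sets for foreign reporter genes were left out, a choice made after a first look at the comparisons, which left 57194. Values were analysed as log2(intensity + 16), which understates the changes of dim probe sets. The upper 60% by mean over the arrays, 34317 probe sets, were tested. A probe table gave 1 gene for 22436 probe sets (17905 genes), several for 95 and none for 34727. All 22436 were found in the reference gene table, which was used for names only, and no genome coordinates were used here. Of the tested probe sets 18460 had 1 gene and 2685 an informative gene name.

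Each of 5 comparisons (tms5 against wild type at high and at low temperature, their interaction, and temperature in wild type and in tms5) was tested with limma 3.58.1 in R 4.3.3, with a group mean model, background as a block and empirical Bayes (3 residual degrees of freedom, prior degrees of freedom 2.16). P-values were two-sided, and probe sets were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Separately, probe sets changed at least 2-fold in the same direction in both backgrounds were counted, beside the count expected from independent lists, the product of the counts of the backgrounds divided by the number tested. That count has no test, since a background has 1 array a side.

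Gene lists were tested with limma's camera at a preset correlation of 0.01, and again with a correlation estimated from the data, adjusted over the 30 lists with at least 5 tested probe sets in a comparison. Of 33 lists, 23 had a theme fixed in advance. Because the tables gave short symbols and no descriptions, members were matched by symbol patterns, written after a first look at the comparisons, and 10 themes were added then (DNA replication, kinesins, cellulose synthases, cytokinin, jasmonate, dehydration and cold, metallothioneins, antioxidant enzymes, sugars and aquaporins). Themes with no usable symbols, such as RNase Z, F-box, pentatricopeptide repeat and tRNA processing genes, peroxidases and late pollen genes, were not analysed here. Fisher's exact test for lists among probe sets changed 2-fold in both backgrounds was added after the data were seen. Within a list, members were also adjusted over the list alone. Correlations across probe sets are descriptive and have no p.

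Named genes followed a fixed rule. The ubiquitin-L40 genes came first. Then, per comparison and direction, probe sets with 1 gene and an informative name that passed the test and had the same direction in both backgrounds were ranked by the smaller of the 2 changes, up to 12. Where fewer than 8 passed, those at least 2-fold changed in both backgrounds followed by the same ranking, up to 8, as not passing the test. For each list, members were picked by the same ranking. Exceptions are stated where they occur, as are the early and late tapetum genes, a split chosen after the data were seen.

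Alternatives were no filter, the upper 40%, no block, only the 4 arrays of a comparison, eBayes with trend and robust, array weights, background by temperature and background by genotype terms, median centring, 1 probe set per gene, 1.5-fold and 3-fold thresholds and leaving out each array in turn. With an array left out, its group held 1 array, which was assumed to vary like the others. The fit then filled its background from the mean gap between backgrounds in the other groups, so the indica temperature gap can enter such means. Added after the data were seen were the deposited values without normalization, offsets of 1 and 64, and the array set (indica low, indica high, japonica) as a block. With noise taken from the fit to all 8 arrays, the pipeline was tested on simulated data of the same size with 50 probe sets changed at each size. It called 1 of 50 changed 2-fold, 36 changed 4-fold, 41 changed 8-fold and 48 changed 16-fold, and 8 of 34117 unchanged ones. Counted as 2-fold in both backgrounds were 14, 47, 49 and 49 of these, and 225 unchanged ones. The simulated noise was independent between arrays, while the error of the real fit takes in the separation of the indica temperatures. These rates therefore need not hold for the real arrays. A simulated list of 20 members shifted by 1 on the log2 scale gave a camera p of 9.07e-32 in limma. Of 20 unshifted lists, 0 passed an unadjusted 0.05. The simulated probe sets varied independently of each other, so these lists do not test the preset correlation against genes that vary together. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.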

Results

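Transcript levels were measured in young rice panicles, taken between the microspore mother cell stage and meiosis, on 8 Affymetrix rice arrays of 57258 probe sets. AnN (indica) and ZH11 (japonica) were the wild types. AnS-1 is an indica TGMS mutant, and Os02g12290iL1 is a japonica line with RNA interference against Os02g12290. The design text calls AnS-1 and Os02g12290iL1 both tms5, and asks about a role of the ribonuclease RNase ZS1 in the metabolism of mRNA. Each line was grown at a day average temperature of 23 °C (low, permissive) or 28 °C (high, restrictive). The 4 groups of genotype and temperature held 2 arrays each, 1 per background, so no line had a replicate at a temperature and the number of arrays limits the precision. P-values measure only the spread between these samples.

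Median deposited intensities were 61.3 for AnN and 59.2 for AnS-1 at low temperature, and 141 for AnN and 139 for AnS-1 at high temperature. In japonica they were 117 for ZH11 and 111 for Os02g12290iL1 at low temperature, and 109 and 115 at high temperature. The indica arrays of the 2 temperatures therefore lay on different scales, and all values below are from quantile normalized arrays. Without that step the median log2 change from low to high temperature was 0.86 in AnN and 0.84 in AnS-1, against -0.10 and -0.13 with it, and the temperature changes below are relative to that shift. The first principal component held 57.9% of the variance and separated the backgrounds, and the second, with 27.6%, separated the indica arrays by temperature. Spearman correlations across probe sets were 0.855 between the AnN arrays of the 2 temperatures and 0.987 between those of ZH11. Between wild type and tms5 they were 0.953 in indica at low temperature, against 0.989 in indica at high temperature and 0.989 and 0.985 in japonica at low and high temperature. The third principal component, with 6.86% of the variance, set AnN at low temperature (-57.5) apart from AnS-1 at low temperature (49.7).

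Ubiquitin-L40 genes, which encode ubiquitin fused to a protein of the large ribosomal subunit and were singled out in advance because of their known link to RNase ZS1, had high intensities on every array. Ub-CEP52-1 (LOC4332169) had 5150 in AnN and 5950 in AnS-1 at low temperature, and 4580 and 4780 at high temperature. Its intensities in ZH11 and Os02g12290iL1 were 6070 and 6150 at low temperature, and 5840 and 5930 at high temperature. Ub-CEP52-2 (LOC4347896) ranged from 3310 in AnN at high temperature to 4730 in AnS-1 at low temperature. The mean log2 difference of tms5 from wild type at high temperature was 0.04 ± 0.03 (SD, n = 2) for Ub-CEP52-1 and 0.03 ± 0.11 (SD, n = 2) for Ub-CEP52-2. At low temperature it was 0.11 ± 0.13 (SD, n = 2) and 0.11 ± 0.06 (SD, n = 2). Neither gene passed the limma test in a comparison, the smallest p adjusted over the list alone being 0.278, for high against low temperature in tms5. The 4 probe sets of other ubiquitin precursor genes differed on average by 0.05 at high temperature and 0.09 at low temperature. The target gene Os02g12290 itself was not analysed here.

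At high temperature, where the design sets tms5 under restriction, 4 of 18 tapetum and pollen wall probe sets were at least 2-fold lower in both tms5 lines, and none of the 18 passed the limma test on all arrays. CYP703A3 (LOC4344594), a fatty acid hydroxylase of pollen wall synthesis, was 6.22-fold lower in AnS-1 than in AnN and 8.40-fold lower in Os02g12290iL1 than in ZH11. C6 (LOC4350790), an anther lipid transfer protein, was 10.3-fold and 5.54-fold lower. CP1 (LOC4337353), a cysteine protease of the tapetum, was at least 3.28-fold and 4.76-fold lower, lower bounds because its 52.8 in AnS-1 and 54.6 in Os02g12290iL1 match a floor of up to 57 on 3 low temperature arrays, and PTC1 (LOC4347213), a regulator of tapetal cell death, had log2 differences of -1.75 and -1.41. By sign, 11 of the 18 were lower in both backgrounds and 1 was higher in both. The count of 4 gave an adjusted p of 0.000113 by Fisher's exact test over the 18460 probe sets with 1 gene, a test added after the data were seen. Members of the list were matched after a first look at the comparisons, and the test treats probe sets as independent. This p is therefore not independent evidence. The mean log2 difference of the list was -0.64, with -0.99 to -0.29 when 1 array was left out, and its medians were -0.24 in indica and -0.16 in japonica. The list passed limma's camera test with its preset correlation (adjusted p = 1.94e-05). It did not with an estimated correlation (adjusted p = 0.934). Leaving out AnN at high temperature gave an adjusted p of 0.0956, and leaving out Os02g12290iL1 at high temperature gave 0.315.

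Other named genes with at least 2-fold lower levels in both backgrounds included NIP4-1, an aquaporin of the NIP family, with a mean log2 difference of -4.79 ± 1.35 (SD, n = 2). HXK6, a hexokinase, was 7.94-fold lower in indica and 8-fold lower in japonica. CHS, a chalcone synthase, had log2 differences of -2.93 and -3.87, while the 2 further probe sets of the gene had -0.07 and 0.18, and -0.10 and -0.01. KPHMT1, an enzyme of pantothenate synthesis, was 4.20-fold and 5.98-fold lower, and the phospholipase A2 gene pla2-II was 2.85-fold and 8.81-fold lower. These 8 genes were listed by size of change and did not pass the limma test on all arrays. In the wild types at high temperature the intensities were 3650 in AnN and 5730 in ZH11 for CYP703A3, 2920 and 3190 for NIP4-1, and 1540 and 1260 for HXK6.

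**Figure D1:**
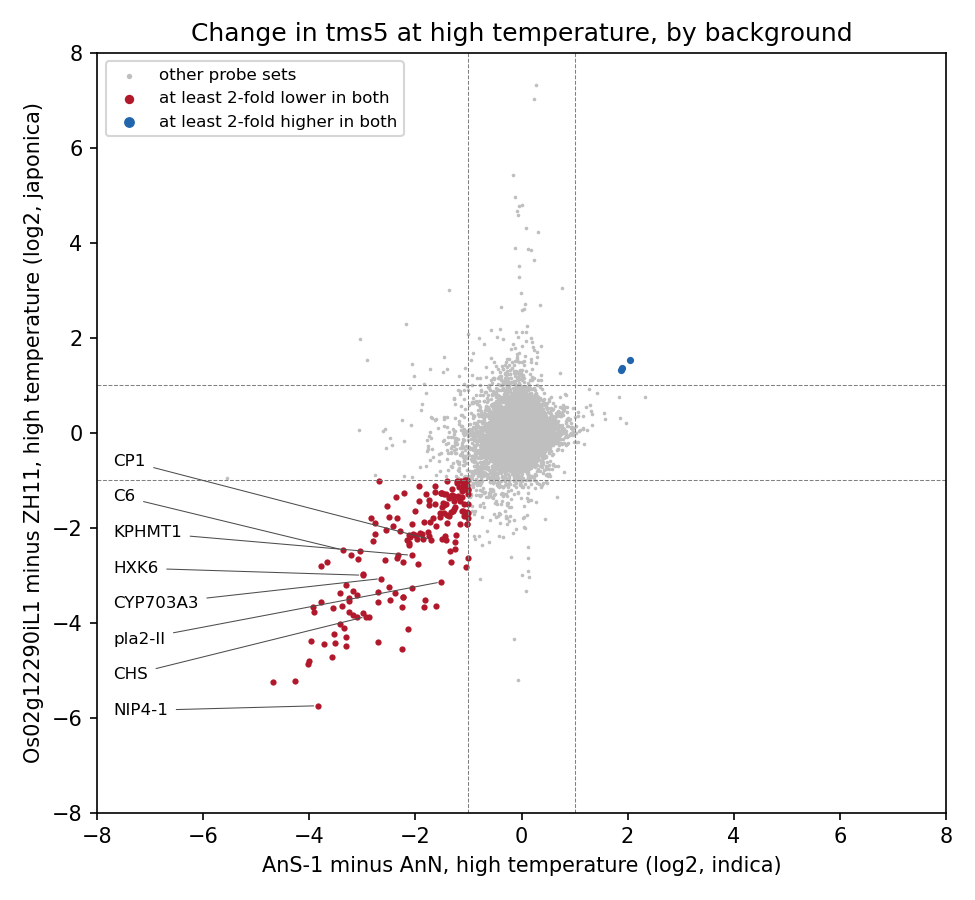
Each point is 1 probe set, with the log2 difference of AnS-1 from AnN at high temperature on the x axis and that of Os02g12290iL1 from ZH11 on the y axis. The 167 red points are at least 2-fold lower in both backgrounds and the 3 blue points at least 2-fold higher in both.

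Over all 34317 tested probe sets, 167 were at least 2-fold lower in both backgrounds at high temperature, where 3.51 were expected from independent lists. Of these, 110 had 1 gene and 16 an informative gene name. Only 3 were at least 2-fold higher in both (0.17 expected), all without a gene here, and 15 were changed in opposite directions (2.29 expected). With all 8 arrays limma called 0 probe sets, and 405 had an unadjusted p under 0.05, where chance gives 1716. Fitted to the 4 arrays of this comparison alone, limma, with 1 residual degree of freedom, called 135 (3 higher, 132 lower), of which 131 were in the set of 167, and 2021 had an unadjusted p under 0.05. In that fit 7 of the 8 listed genes were called, with adjusted p from 0.00225 for HXK6 to 0.0324 for NIP4-1, and pla2-II was not (adjusted p = 0.189). With the array set as a block none of the 8 was (adjusted p from 0.0988 for CYP703A3 to 1). For this comparison the array set as a block and a term for background by temperature are the same fit. In it 3 probe sets were called, all lower, namely LOC4339758 (log2 differences of -3.30 and -3.20) and 2 without a gene here, named after their values were seen.

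**Figure D2:**
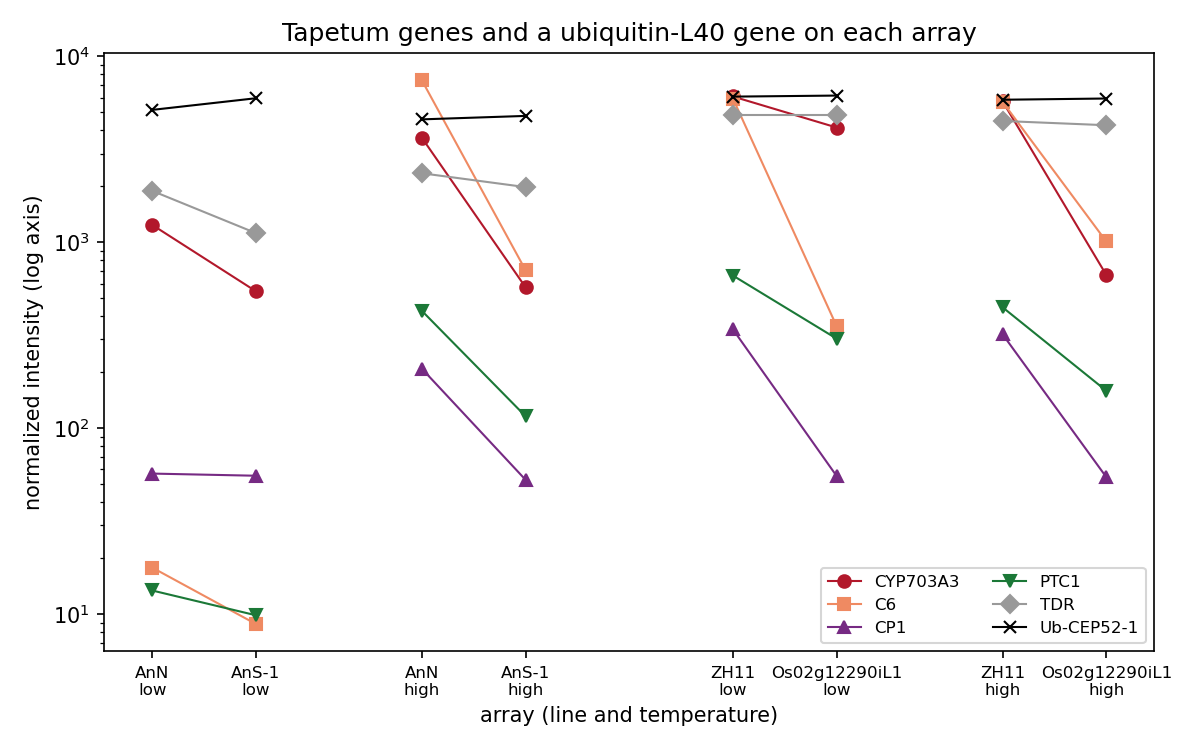
Normalized intensity on a log axis (y) of 5 tapetum genes and the ubiquitin-L40 gene Ub-CEP52-1 on each of the 8 arrays (x), with lines joining wild type and tms5 of a background and temperature. At high temperature CYP703A3 had 3650 in AnN and 573 in AnS-1, and 5730 in ZH11 and 668 in Os02g12290iL1, while Ub-CEP52-1 stayed between 4580 and 6150 on all arrays.

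Meiosis genes, by contrast, showed no decrease at high temperature, with medians of 0.17 in indica and 0.04 in japonica and 0 of 18 probe sets at least 1.5-fold lower in both backgrounds (adjusted p = 0.0764). Ranked by the smaller of the 2 changes, MEL1, a germline argonaute, came first in that list with log2 differences of 0.87 and 0.32. The camera test with its preset correlation called 3 further lists, none of them with an estimated correlation (adjusted p = 0.934 for each). Glutathione S-transferases, which conjugate toxic compounds, were lower (7 probe sets, mean -0.38, 4 lower in both, adjusted p = 0.0178), with -0.41 and -1.72 for GSTU1. Cell wall loosening expansins were higher (24 probe sets, mean 0.16, 14 higher in both, adjusted p = 0.0178), with 0.26 and 0.73 for EXPA1. Cytosolic ribosomal proteins were higher by a small amount (40 probe sets, mean 0.07, 23 higher in both, adjusted p = 0.038). Leaving out 1 array gave means of -0.58 to -0.17, -0.04 to 0.35 and 0.03 to 0.11 for these 3 lists. The glutathione S-transferase call was lost without AnN (adjusted p = 0.335) or Os02g12290iL1 (adjusted p = 0.587) at high temperature, and without a background block (adjusted p = 0.106). The expansin call was lost without AnS-1 (adjusted p = 0.382) or ZH11 (adjusted p = 0.782) at high temperature. The ribosomal call was lost without any of AnN, AnS-1 or Os02g12290iL1 at high temperature (adjusted p = 0.958, 0.154 and 0.315), without either wild type at low temperature (adjusted p = 0.0714) and with median centring (adjusted p = 0.253). For lipid transfer proteins the mean was negative (-0.36), with C6 among them, while their median (0.19) and test were positive (adjusted p = 0.707). Of the 150 list tests in all comparisons, 19 had a mean, median or test of another sign, and 0 of these were called. Adjusted over the list alone, 1 probe set was called, in the cytokinin list (adjusted p = 0.00641).

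At low, permissive temperature, the 8 genes listed by size of change between tms5 and wild type were all lower in tms5, and none passed the limma test. The mannose-binding lectin gene salT was 11.3-fold lower in AnS-1 than in AnN and 8.63-fold lower in Os02g12290iL1 than in ZH11. The chitinase gene Chib3H-a was 7.36-fold and 7.42-fold lower, and a further gene named chitinase (LOC4342115) was at least 3.62-fold and 5.77-fold lower, the former a lower bound because it was near background in AnS-1 (17.2). The peroxygenase gene PXG was 5.24-fold and 6.25-fold lower, the metallothionein gene MT1A 4.46-fold and 8.22-fold, and the lipoxygenase gene LOX1.1 3.66-fold and 3.97-fold. MS (log2 differences of -3.27 and -2.30) and the germin-like gene GER2 (-2.51 and -1.87) completed the 8.

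At low temperature 18 gene lists passed the camera test with its preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.534. Among them, the jasmonate, dehydration and cold, DNA replication, kinesin, cytokinin, metallothionein, sugar, aquaporin and cellulose themes were added after a first look at the comparisons. Leaving out AnS-1 at low temperature ended 15 of the 18, with adjusted p from 0.391 to 0.945, and leaving out ZH11 at low temperature ended 13, with adjusted p from 0.0996 to 0.698. The means of 7 turned sign without AnS-1 and of 2 without AnN at low temperature, and 16, 8, 11 and 16 moved by over 1.5 times without AnS-1, AnN, ZH11 and Os02g12290iL1 at low temperature. Chitinases and pathogenesis-related proteins were lower (13 probe sets, mean -0.91, 9 lower in both, adjusted p = 1.95e-05). So were jasmonate genes (30, mean -0.47, 18 lower in both, adjusted p = 1.95e-05), with -3.19 and -1.71 for the transcription factor JAMYB. Dehydration and cold response genes had a mean of -0.63 (23 probe sets, 11 lower in both, adjusted p = 0.00219), and photosynthesis genes one of -0.37 (16, 14 lower in both, adjusted p = 1.17e-05), with -1.04 and -0.46 for RBCS, the small subunit of Rubisco. DNA replication factors were higher (35, mean 0.41, 30 higher in both, 0 lower in both, adjusted p = 2.99e-06), with 0.74 and 0.35 for ORC5 of the origin recognition complex, but without AnS-1 at low temperature their mean was -0.02 (adjusted p = 0.945). Kinesins (35, mean 0.25, 27 higher in both, adjusted p = 0.000319), cyclins and cell division kinases (24, mean 0.24, 17 higher in both, adjusted p = 0.0134) and meiosis genes (18, mean 0.24, 12 higher in both, adjusted p = 0.0135) were higher too. Their medians were larger in indica than in japonica, at 0.71 and 0.11 for DNA replication factors and 0.33 and 0.12 for meiosis genes. The meiotic genes SPO11-2, MSH5 and MER3 had log2 differences of 0.90 and 0.23, 0.84 and 0.27, and 0.41 and 0.29.

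The other 10 of the 18 lists were likewise called with the preset correlation and not with an estimated one. Small RNA machinery (mean 0.19, adjusted p = 0.0135), cytosolic ribosomal proteins (mean 0.07, adjusted p = 0.00209) and 26S proteasome subunits (mean 0.12, adjusted p = 0.0423) were higher. Cytokinin genes (mean -0.22, adjusted p = 0.000891), lipid transfer proteins (mean -0.63, adjusted p = 0.00209), aquaporins (mean -0.23, adjusted p = 0.014) and metallothioneins (mean -0.44, adjusted p = 0.0188) were lower. Sugar metabolism and transport genes (mean -0.13, adjusted p = 0.031), glutathione S-transferases (mean -0.32, adjusted p = 0.0401) and cellulose and glucan synthases (mean -0.07, adjusted p = 0.0485) were lower too. Without AnN at low temperature 3 were lost, among them ribosomal proteins (adjusted p = 0.095), and without Os02g12290iL1 the cytokinin (adjusted p = 0.16) and metallothionein (adjusted p = 0.281) calls were. The proteasome and cellulose calls were also lost without any of the 4 arrays at high temperature, with adjusted p from 0.0508 to 0.0561, and with median centring (adjusted p = 0.0504). Without the block the glutathione S-transferase (adjusted p = 0.196), cellulose (0.233) and aquaporin (0.0624) calls were lost, with the array set as a block the cellulose (0.114) and sugar (0.0565) calls, and without a filter the sugar call (0.108). Adjusted over the list alone, 2 dehydration and cold probe sets were called (smallest adjusted p = 0.0226) and 1 each of the chitinase (adjusted p = 0.00932), jasmonate (adjusted p = 0.0263) and cytokinin lists (adjusted p = 0.0365).

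Probe sets at least 2-fold lower in both backgrounds at low temperature numbered 119, against 10.5 expected, and 6 were higher, against 1.30. In indica alone 781 were higher and 1281 lower, and in japonica 57 and 280. Of the 119, 96 had 1 gene and 16 an informative name. In opposite directions 7 changed, where 8.50 were expected. The 6 higher ones held 3 genes, LOC4340083 (log2 differences of 1.11 and 1.63), LOC4335658 (2.32 and 1.58) and LOC4347693 (1.98 and 3.32), named after their values were seen. With all arrays limma called 0, with 738 at an unadjusted p under 0.05 and a smallest adjusted p of 0.745. The fit to the 4 arrays of the comparison also called 0, and leaving out Os02g12290iL1 at low temperature gave 35 (11 higher, 24 lower). The tapetum genes C6 (17.8 and 8.85) and PTC1 (13.4 and 9.86) were near background on both indica arrays at low temperature, so the indica differences of these genes there carry little signal. C4 was not, with 3610 in AnN and 374 in AnS-1, but in japonica it had 11200 in ZH11 and 10100 in Os02g12290iL1. In ZH11 and Os02g12290iL1 at low temperature C6 had 5930 and 354, PTC1 662 and 303, and CP1 340 and 55.3, while CP1 had 57 and 55.5 in AnN and AnS-1. The tapetum and pollen wall list had a mean of -0.37 at low temperature, with 10 of 18 lower in both backgrounds, and was not called (adjusted p = 0.0564, and 0.0239 with the array set as a block).

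**Figure D3:**
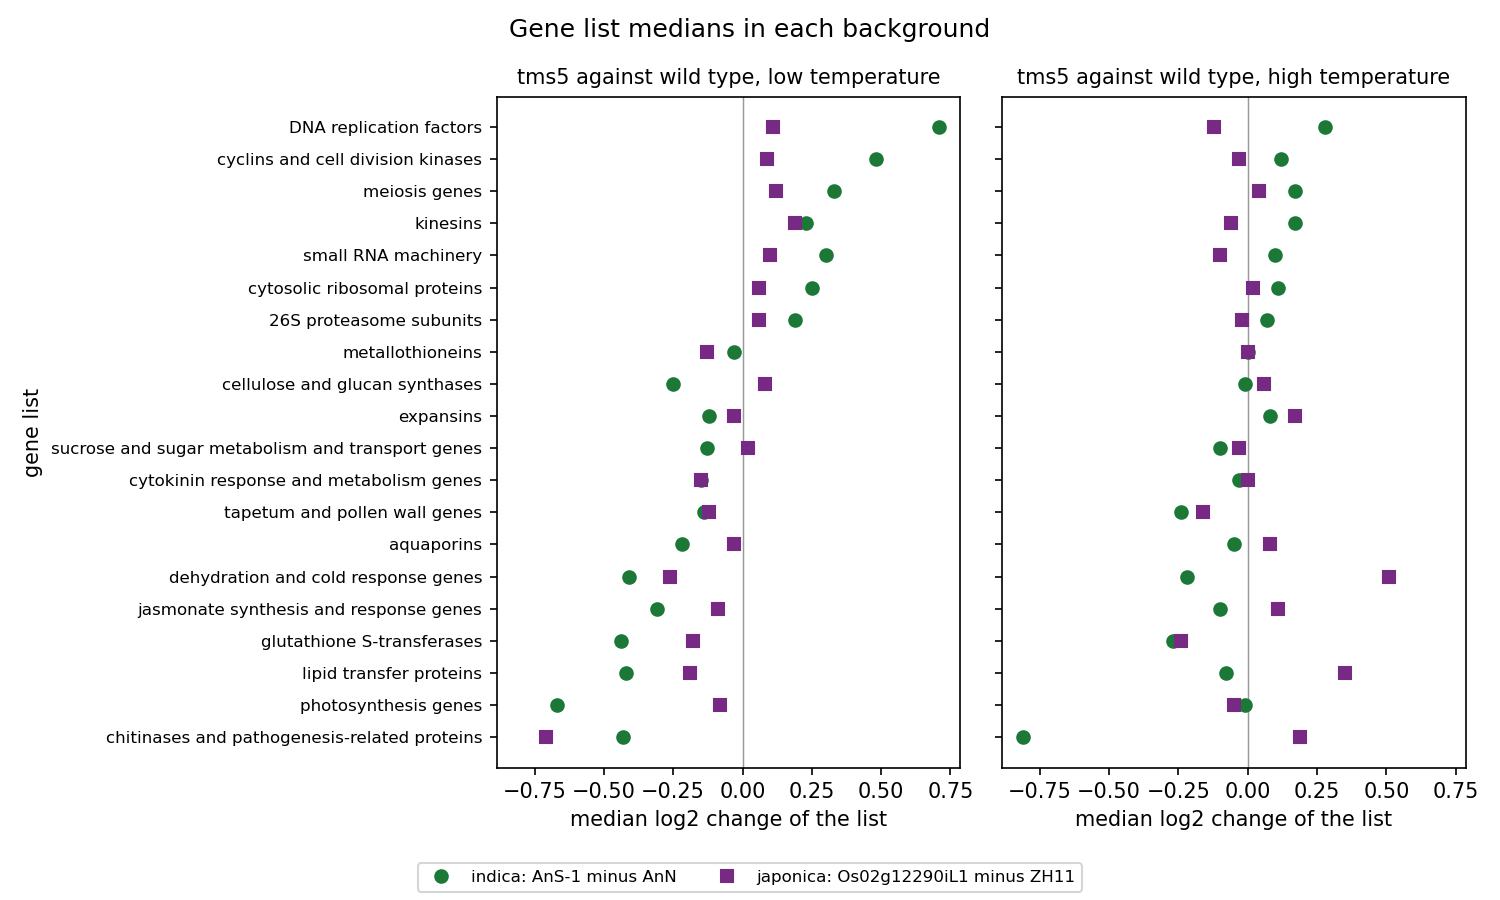
Median log2 difference between tms5 and wild type (x) of each gene list that passed the camera test with its preset correlation at either temperature (y), with circles for indica and squares for japonica. No list passed with an estimated correlation. At low temperature the DNA replication factors had medians of 0.71 and 0.11, and the chitinases and pathogenesis-related proteins -0.43 and -0.71.

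The change of the tms5 difference from low to high temperature was tested as an interaction, and none of the genes listed for it by the smaller of the 2 changes passed the limma test. In both backgrounds salT was relatively higher at high temperature (interaction of 3.30 and 3.04 on the log2 scale), as were LEA19 (2 and 1.97) and PM19L (1.59 and 2.12), genes of dehydration tolerance. Further genes with positive values were MS (2.19 and 1.71), the metallothionein gene MT1B (1.64 and 2.18), Chib3H-a (1.30 and 3.0), the glutaredoxin gene GRXS5 (1.40 and 1.30) and the low temperature induced gene LTI6B (1.84 and 1.27). Negative values were listed for NIP4-1 (-3.48 and -2.67), KPHMT1 (-1.96 and -1.99) and CYP703A3 (-1.47 and -2.52). The mitotic cyclin gene CycB1-1 (-1.37 and -2.17), the zinc finger gene OsC3H47 (-1.65 and -1.29) and pla2-II (-1.17 and -1.27) completed the list. At low and high temperature NIP4-1 had 148 and 2920 in AnN, and 111 and 189 in AnS-1. KPHMT1 had 259 and 863 in AnN, and 239 and 193 in AnS-1. The values of pla2-II were 142 and 742 in AnN, and 109 and 250 in AnS-1. Low levels in AnN at low temperature left less room for a decrease in AnS-1. For NIP4-1, KPHMT1 and pla2-II the indica values thus do not show that an effect of tms5 depends on temperature.

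The camera test for this interaction called 10 lists, all detailed in the closing section, and their smallest adjusted p with an estimated correlation was 0.858. Dehydration and cold response genes had a mean of 0.85, and 6 of 23 were at least 2-fold higher in both backgrounds (Fisher's exact test, adjusted p = 2.68e-08). That theme, its members and Fisher's test were chosen after a first look at the comparisons, so this p is not independent evidence. The jasmonate, DNA replication and kinesin themes were added then too. Chitinases and pathogenesis-related proteins had a mean of 0.75 (adjusted p = 0.00732), while DNA replication factors had one of -0.30 (29 of 35 lower in both, adjusted p = 0.00214). All 10 calls were lost without AnS-1 at low temperature (adjusted p from 0.295 to 0.971) and without ZH11 at low temperature (from 0.0576 to 0.661). Without ZH11 at high temperature 9 were lost (from 0.74 to 0.992), and without AnS-1 at high temperature 6 were (from 0.0622 to 0.51). The means of 5 lists turned sign without AnS-1 at low temperature, of 6 without ZH11 at high temperature and of 1 without ZH11 at low temperature. Photosynthesis genes lost their call without AnN at low (adjusted p = 0.281) or high temperature (adjusted p = 0.0894), and small RNA machinery without Os02g12290iL1 at high temperature (adjusted p = 0.0915). Without the block the cyclin (adjusted p = 0.0875), lipid transfer (0.157) and small RNA (0.0516) calls were lost, and without a filter the chitinase (0.0794) and expansin (0.0719) calls. By size, 110 probe sets were at least 2-fold higher in both backgrounds (11 expected) and 76 lower (5.39 expected), with 23 in opposite directions. Called by limma were 0, with 183 at an unadjusted p under 0.05.

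In wild type, the genes listed by size of change with temperature included heat shock protein genes, which were higher at high temperature, and the clock gene CCA1, which was lower, and none passed the limma test. HSP23.2, HSP26.7 and HSP17.4, small heat shock proteins, were 15.6-fold, 5.86-fold and 3.56-fold higher at high temperature in AnN (the first 2 from a dim 31.6 and 31.9 at low temperature), and 4.42-fold, 2.36-fold and 2.05-fold higher in ZH11. CCA1 was 11.5-fold lower in AnN and 4.31-fold lower in ZH11, and DTH7, a regulator of flowering time, 5.28-fold and 2.35-fold lower. The meiotic recombinase gene DMC1 was 2.19-fold and 2.96-fold lower, and the zinc finger gene OsC3H43 2.16-fold and 2.26-fold. GER2 (3.23-fold and 2.66-fold) and the chitinase gene Cht1 (5.07-fold and 2.31-fold) were higher.

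As a list, heat shock proteins were higher in wild type at high temperature (28 probe sets, mean 0.92, 20 higher in both, adjusted p = 8.37e-07). The list passed without each of the 8 arrays in turn, with means of 0.56 to 1.29 and a largest adjusted p of 7.05e-05, but not with an estimated correlation (adjusted p = 0.959). Its medians were 1.37 in indica and 0.24 in japonica. Chitinases and pathogenesis-related proteins were higher (mean 0.84, 7 of 13 in both, adjusted p = 0.0113). That call was lost with an estimated correlation (adjusted p = 0.959), without AnN at low (adjusted p = 0.0718) or high temperature (adjusted p = 0.986) and with the array set as a block (adjusted p = 0.367), and its mean was 0.02 to 1.65 with 1 array left out. Its medians were 2.28 and 0.07, and 1 of its probe sets was called adjusted over the list alone (adjusted p = 0.0418). Counted by size, 28 probe sets were at least 2-fold higher in both backgrounds (15.4 expected) and 35 lower (11.6 expected), and 58 moved in opposite directions (28.4 expected). In the deposited values 53 were higher and 15 lower in both. AnN had 3659 probe sets at least 2-fold higher and 2240 lower, and ZH11 144 and 178. Among all tested probe sets limma called 0, with 2057 at an unadjusted p under 0.05, and 4007 (2161 higher, 1846 lower) once a background by temperature term was added. With the array set as a block it called 0 (smallest adjusted p = 0.425). Both fits take the gap between the temperature changes of the backgrounds out of the error, but the block leaves the temperature change to japonica alone, since temperature coincides with the array set in indica, so the 4007 depend on indica arrays in which temperature and array set are not separable.

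None of the genes listed by size of change between temperatures in tms5 passed the limma test. At high against low temperature LOC4342115, named chitinase, was at least 9.57-fold higher in AnS-1 (from 17.2, near background) and 17.7-fold higher in Os02g12290iL1, salT 7.80-fold and 14.5-fold, Chib3H-a 5.04-fold and 7.57-fold, and GER2 5.01-fold and 14.8-fold. The sugar transporter gene MST3 (4.17-fold and 9.34-fold), MS (3.73-fold and 5.79-fold), the mini zinc finger gene MIF1 (3.22-fold and 3.16-fold) and the dehydrin gene rab25 (4.60-fold and 3.14-fold) were also higher. Lower were CCA1 (6.61-fold and 4.28-fold), OsC3H43 (3.90-fold and 2.52-fold), OsC3H47 (2.14-fold and 3.08-fold) and the aquaporin gene PIP2-4 (2.49-fold and 2.19-fold). The copper transporter gene COPT1 (2.36-fold and 2.04-fold), the iron transporter gene VIT1.2 (6.35-fold and 2.02-fold) and the cytokinin response regulator gene RR9 (2.43-fold and 2.01-fold) were lower too.

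For temperature in tms5, 14 lists passed the camera test with its preset correlation, and all 14 calls were lost with an estimated one (smallest adjusted p = 0.618). The jasmonate, dehydration and cold, cellulose, kinesin and DNA replication themes among them were added after a first look at the comparisons. Without AnS-1 or Os02g12290iL1 at low temperature the means of 13 and 8 of the lists moved by over 1.5 times, and without AnS-1 at high temperature those of 3, with that of DNA replication factors at 0 without AnS-1 at low temperature. Chitinases and pathogenesis-related proteins (mean 1.59, 11 of 13 higher in both, adjusted p = 4.41e-06), heat shock proteins (mean 0.81, 16 of 28, adjusted p = 2.39e-05), jasmonate genes (mean 0.69, 19 of 30, adjusted p = 0.000103) and dehydration and cold genes (mean 0.96, 15 of 23, adjusted p = 0.000141) were higher. Expansins (mean 0.36, adjusted p = 0.000857), lipid transfer proteins (mean 0.85, adjusted p = 0.00556) and cellulose and glucan synthases (mean 0.13, adjusted p = 0.0339) were higher too. Cyclins and cell division kinases (mean -0.59, 17 of 24 lower in both, adjusted p = 0.000533), 26S proteasome subunits (mean -0.30, adjusted p = 0.000857) and small RNA machinery (mean -0.30, adjusted p = 0.00231) were lower. So were kinesins (mean -0.35, adjusted p = 0.00267), DNA replication factors (mean -0.43, adjusted p = 0.00281), ribosomal proteins (mean -0.14, adjusted p = 0.00556) and meiosis genes (mean -0.33, adjusted p = 0.0339). The array set as a block leaves the temperature change to japonica alone. With it 5 were lost, namely meiosis (adjusted p = 0.955), DNA replication (0.912), lipid transfer (0.326), dehydration and cold (0.092) and kinesins (0.0553). Without AnS-1 at low temperature 6 were lost (adjusted p from 0.0567 to 0.916), and without Os02g12290iL1 at high temperature 4 (from 0.0584 to 0.252). Meiosis genes lost their call without AnS-1 at high temperature (adjusted p = 0.162), and with cellulose synthases also without either wild type at low temperature (adjusted p = 0.0523 and 0.0645) and without the block (adjusted p = 0.055 and 0.131). The cellulose call was also lost with median centring (adjusted p = 0.0521). Adjusted over the list alone, 4 chitinase probe sets (smallest adjusted p = 0.0111), 2 dehydration and cold probe sets (0.0312) and 1 meiosis probe set (0.0496) were called.

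At least 2-fold higher in both tms5 lines at high temperature were 152 probe sets (34.1 expected), and 57 were lower (22.3 expected), with 67 in opposite directions (57.4 expected). The deposited values gave 224 and 15. Again limma called 0, with 1829 at an unadjusted p under 0.05 and a smallest adjusted p of 0.312. Without Os02g12290iL1 at low temperature it called 29 (19 higher, 10 lower), and with a background by temperature term 4544 (2660 higher, 1884 lower), against 0 with the array set as a block (smallest adjusted p = 0.152).

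Across probe sets, which are not independent replicates, the changes of the backgrounds correlated with r = 0.356 and rho = 0.066 for tms5 at high temperature, and with r = 0.269 and rho = 0.309 at low temperature. The interaction gave r = 0.224 and rho = 0.273. For temperature the values were r = 0.024 and rho = 0.087 in wild type and r = 0.206 and rho = 0.251 in tms5. Within a background, the tms5 difference at low temperature correlated with that at high temperature with r = 0.275 and rho = 0.287 in indica and with r = 0.301 and rho = -0.051 in japonica.

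The 167 probe sets lower at high temperature had a median log2 difference of -0.96 at low temperature in japonica, where 81 (48.5%) were at least 2-fold lower, against 0.816% of all probe sets. In indica the median was -0.32, and 37 (22.2%) were at least 2-fold lower, against 3.73% of all. The shared lower sets of the 2 temperatures had 10 probe sets in common.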

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

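The tests of explanations for the 2 patterns weighed here, and the look at reporter probe sets, were chosen after the results were seen.

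For 10 gene lists the difference of tms5 from wild type was not the same at high as at low temperature, by limma's camera on the interaction with its preset correlation. With an estimated correlation none was called (adjusted p = 0.858 for each), all 10 calls were lost without AnS-1 or without ZH11 at low temperature (adjusted p from 0.295 to 0.971 and from 0.0576 to 0.661), and 9 without ZH11 at high temperature (from 0.74 to 0.992). Leaving out AnS-1 at high temperature ended 6 (from 0.0622 to 0.51). A leave-out fit fills the missing array from the other background and the mean gap between backgrounds, which in indica differs by temperature. A turned sign can therefore come from a single array or from this filling. For DNA replication factors, most probe sets were lower in both backgrounds, which share no array. For 6 of the lists leaving out 1 array turned the sign of the mean. Their ranges were -0.06 to 1.56 for chitinases, -0.04 to 0.75 for jasmonate, -0.38 to 0.93 for lipid transfer, -0.73 to 0.14 for DNA replication, -0.55 to 0.06 for cyclins and -0.43 to 0.04 for kinesins, while the other lists kept their sign, at 0.22 to 1.49 for dehydration and cold, 0.02 to 0.5 for photosynthesis, 0.06 to 0.44 for expansins and -0.33 to -0.07 for small RNA machinery. The mean change of that difference, on the log2 scale, was 0.85 for dehydration and cold response genes (adjusted p = 0.00214), 0.75 for chitinases and pathogenesis-related proteins (adjusted p = 0.00732) and 0.36 for jasmonate genes (adjusted p = 0.00732). It was 0.27 for lipid transfer proteins (adjusted p = 0.00732), 0.26 for photosynthesis genes (adjusted p = 0.0139) and 0.25 for expansins (adjusted p = 0.00898). On all arrays the mean was negative for lists of dividing cells, with -0.30 for DNA replication factors (adjusted p = 0.00214), -0.25 for cyclins and cell division kinases (adjusted p = 0.041) and -0.20 for kinesins (adjusted p = 0.0114). Small RNA machinery had -0.20 (adjusted p = 0.0105), with 17 of 21 probe sets lower in both backgrounds. The dehydration and cold, jasmonate, DNA replication and kinesin themes were added after a first look at the comparisons.

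Signal was also seen in the 64 control probe sets for foreign reporter genes, which no comparison uses. One of them had intensities of 3080 to 3220 on both Os02g12290iL1 arrays and at most 30.9 on the others, a lowest ratio of 66 with the offset of 16 added. Another had 2280 to 2840 against at most 76.1, a ratio of 24.9. None was bright in AnS-1, and the highest ratio of the other control probe sets was 1.02.

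The first pattern is the set of 167 probe sets lower in tms5 at high temperature in both backgrounds, which holds tapetum genes such as CYP703A3 and C6. Chance overlap of independent lists is argued against by a count 47.6 times the expected one. That count alone does not exclude wide variation, since simulated arrays gave 225 unchanged probe sets at least 2-fold in both backgrounds, 119 lower and 106 higher. The simulation, though, had 218 in opposite directions. Here 11.1 times as many were lower in both as in opposite directions (15, where 2.29 were expected). That argues against probe sets that vary widely and independently on every array. It cannot exclude genes that vary together between panicles. With 1 pair per background, such a group can fall lower in both. A scaling difference between arrays that moves probe sets of like intensity together is argued against by the 12394 others in each background whose wild type intensity lay between the quartiles of the set. Their median log2 change in the deposited values was -0.01 in indica (SD 0.26) and -0.01 in japonica (SD 0.27), against -1.97 and -2.07 for the set. With a loss of anther cells of every kind, most meiosis probe sets should be lower too, and 0% of 18 were at least 1.5-fold lower in both. That argues against such a loss only among panicles of like stage, which was not shown. Panicles of tms5 harvested at an earlier stage cannot be told apart from a block after the early tapetum steps. Early tapetum genes had medians of 0.07 in indica and -0.11 in japonica and late ones -0.32 and -0.20, all within 1.5-fold, and 1 of 6 early (EAT1) and 4 of 11 late probe sets were at least 1.5-fold lower in both, so either would hold for only some late genes. A candidate explanation from the design is an effect of tms5 on a part of the late tapetum genes at the restrictive temperature. It would cover only the few of the 167 that are in the tapetum list. In japonica it may also hold at the permissive temperature, where 48.5% of the set was at least 2-fold lower. There C6 had 5930 in ZH11 and 354 in Os02g12290iL1. An earlier harvest was not excluded, and the explanation remains a hypothesis found in these data.

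The second pattern is the separation of the indica arrays by temperature, with 3659 probe sets at least 2-fold higher and 2240 lower in AnN. A temperature response of the same size in both backgrounds is argued against by the counts themselves, with 144 higher and 178 lower in ZH11. That only 1.07% of the AnN probe sets changed likewise in ZH11 adds little, since these counts kept the share low in advance. A plain difference of scale between sets of arrays is argued against, since the separation remained after quantile normalization. Spearman correlations, which do not depend on scale, were 0.855 in AnN and 0.851 in AnS-1 between temperatures. They were 0.987 in ZH11 and 0.986 in Os02g12290iL1. A difference of another kind between the sets, such as panicle stage at harvest, cannot be told apart from a stronger response of the indica lines. Each indica temperature forms its own set. C6, for one, had 17.8 in AnN at low and 7440 at high temperature, against 5930 and 5690 in ZH11. The deposited medians differed by 1.04 on the log2 scale between the indica temperatures and by -0.03 between the japonica ones. Quantile normalization removed that difference before the pattern was measured, so it does not decide between these explanations. Differences of tms5 from wild type at 1 temperature are taken within a set, but the limma error on all arrays takes in the separation of the indica temperatures. At high temperature limma called 0 on all arrays (405 at an unadjusted p under 0.05), 3 with the array set as a block and 135 on the 4 arrays of the comparison (2021).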

How the results depend on the processing

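The offsets, the deposited values and the array set block were chosen after the data were seen, and the other alternatives before. At high temperature, limma called 135 probe sets for tms5 with only the 4 arrays of the comparison, against 0 on all arrays. It called 3 with a background by temperature term or the array set as a block, which are the same fit for this comparison. The background by temperature term called 4007 for temperature in wild type and 4544 in tms5, whereas the array set as a block called 0 in both (smallest adjusted p of 0.425 and 0.152). Leaving out 1 array gave 0 to 35 for tms5 at low temperature and 0 to 29 for temperature in tms5, both highest without Os02g12290iL1 at low temperature, and 0 elsewhere. Each such term or subset removes a part of the spread from the error, but the cause was not tested. For the counts in both backgrounds, 1.5-fold and 3-fold thresholds gave 353 and 90 for tms5 at high temperature, 365 and 53 at low temperature, 651 and 52 for the interaction, 453 and 11 for temperature in wild type and 883 and 48 in tms5, as a threshold does by construction. An offset of 64, which shrinks changes of dim probe sets, lowered the last 2 to 30 and 119. Other alternatives left the counts on the same side or within 1.5 times. Of the 167 probe sets lower at high temperature, 165 were kept with median centring, 160 in the deposited values and 128 with an offset of 64.

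For single lists, 1653 results were the same, 156 lost and 102 gained a call in the same direction, and 39 had a mean of the other sign, of which 23 lost and 16 gained a call and 0 were called in both directions. With the array set as a block, which leaves a temperature change to japonica alone, 2 means turned. They were 0.24 for DNA replication factors with temperature in wild type and -0.25 for heat stress transcription factors in tms5. Over the leave-outs of 1 array, the lists that turned had these ranges of the mean. For tms5 at high temperature they were -0.38 to 0.35 for heat shock proteins, -0.29 to 0.18 for heat stress factors, -0.28 to 0.28 for cyclins, -0.47 to 0.86 for WRKY factors, -0.97 to 0.65 for chitinases, -1.01 to 0.3 for lipid transfer proteins, -0.04 to 0.35 for expansins, -0.3 to 0.52 for DNA replication, -0.18 to 0.29 for kinesins and -0.41 to 0.86 for dehydration and cold genes. At low temperature they were -0.04 to 0.19 for ribosomal proteins, -0.06 to 0.3 for the proteasome, -0.05 to 0.53 for meiosis, -0.06 to 0.55 for cyclins, -0.02 to 0.84 for DNA replication, -0.15 to 0 for cellulose synthases and -0.46 to 0 for aquaporins. For the interaction they were -0.55 to 0.06 for cyclins, -0.06 to 1.56 for chitinases, -0.38 to 0.93 for lipid transfer, -0.73 to 0.14 for DNA replication, -0.43 to 0.04 for kinesins and -0.04 to 0.75 for jasmonate. With temperature in wild type they were -0.08 to 1.23 for lipid transfer, -0.54 to 0.27 for DNA replication and -0.53 to 0.74 for dehydration and cold, and in tms5 -0.86 to 0 for DNA replication and -0.07 to 0.12 for sugar genes. Of the settings, the one without ZH11 at high temperature gave the most gains, with 16 for tms5 at high temperature and 11 for temperature in wild type. For named genes, 1140 were the same and 29 gained a call. Of the correlations between backgrounds 8 were the same and 2 moved without the filter. All list calls were lost with an estimated correlation. Quantile normalization as an alternative was not run, since it became the main choice, and a fit to 4 arrays does not exist for the interaction. Background limits the dimmest genes, such as C6 at 17.8 and 8.85 in the indica lines at low temperature.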

Other observations

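At high temperature 201 probe sets were at least 2-fold higher and 355 lower in Os02g12290iL1 than in ZH11, of which 3 and 167 changed likewise in indica. At least 4-fold higher at both temperatures in Os02g12290iL1 than in ZH11, and within 2-fold in indica, were 7 probe sets, and 2 were lower. LOC4331398 led them with log2 differences of 7.33 and 7.03 by 2 probe sets at high temperature and 6.44 and 6.51 at low temperature, followed, by the smaller of the 2 changes, by a probe set without a gene here (3.85 at high and 4.68 at low temperature) and LOC4340325 (3.51 and 3.98). The others had no gene here either, and all were named after their values were seen. At high temperature alone 17 were at least 4-fold higher in that line, among them LOC4331572 with a log2 difference of 4.79 at high and 0.01 at low temperature.

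Differences present at both temperatures were mostly lower levels in tms5. In japonica 131 probe sets were at least 2-fold lower at both temperatures (2.9 expected from independent lists) and 17 higher (0.334 expected), and in indica 113 were lower (12.7 expected) and 6 higher (0.66 expected). Lower at both temperatures in both backgrounds were 10.

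The set of 167 had a median intensity of 650 in AnN and 712 in ZH11 at high temperature, and of 121 in AnS-1, with quartiles of 71 and 306 in Os02g12290iL1, having been chosen on these arrays. At low temperature its medians were 834 in ZH11, 354 in Os02g12290iL1, 154 in AnN and 111 in AnS-1. The tapetum regulator genes EAT1 and TDR, which are not in the set, had log2 differences at high temperature of -0.87 and -0.59 for EAT1 and -0.24 and -0.07 for TDR.

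Lists without a call in any comparison, with their smallest adjusted p by camera, were ubiquitin-conjugating and U-box enzymes (0.118), heat stress transcription factors (0.424), MADS-box transcription factors (0.0753), histones (0.0887) and auxin response genes (0.479). The same held for gibberellin metabolism genes (0.338), WRKY transcription factors (0.0789), endoplasmic reticulum folding proteins (0.182) and antioxidant enzymes (0.0789). Seed storage proteins had 4 tested probe sets, too few for the set test, with a mean log2 difference of -0.01 for tms5 at high and -0.04 at low temperature.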
